A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

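Gene expression was measured by RNA sequencing in 8 libraries of Saccharomyces cerevisiae, prepared from total RNA with the NEBNext Ultra RNA kit, per the labels' protocols. The libraries fall into 4 groups of 2 by strain (mutation strain or control strain) and by title (HP or nHP). Reads were processed with TopHat2 version 2.0.9, per the submitters' processing notes. The counting program, its strand setting, the genome build and the gene annotation are not given in the sources used here. Reads of overlapping or antisense genes therefore cannot be told apart, and no coordinates are printed.

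The deposited counts are whole numbers of reads per gene, with 1 column per library and no normalization. The deposited RPKM values (reads per kilobase of gene, scaled to the library total) equal the counts divided by the column total and by 1 length per gene shared by all libraries, which was checked on the values. A deposited summary of how many genes fall in each RPKM range was not used. The tables hold 7126 genes, and 6048 of their IDs matched a name in the R64 reference gene table, which was used for names only. The 1078 unmatched IDs held 0.361% to 0.479% of the counts of a library.

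Differences were computed from the counts with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed by edgeR's standard filter on the group design, which left 6174 genes, and library sizes were scaled by TMM, a correction for differences in composition. All 8 libraries entered 1 quasi-likelihood model of the 4 group means, with 4 residual degrees of freedom. Its common dispersion was 0.00651, equal to a variation of 8.07% between libraries of a group, with 7.40 prior degrees of freedom. The comparisons were mutation against control strain within nHP and within HP, HP against nHP within each strain, and the interaction, which is the HP difference of the mutation strain minus that of the control strain. A gene was called when edgeR's quasi-likelihood F test, which is two-sided, gave a p below 0.05 after Benjamini-Hochberg adjustment over all genes tested. Standard errors of log2 fold changes were derived from the F statistic. CPM means counts scaled to a library total of 10 to the power of 6, after TMM.

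Before the data were examined, the comparisons, the alternative settings, 32 gene lists and the rule for named genes were fixed. Lists with at least 5 measured members, 29 in number, were tested with limma 3.58.1's camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. Neither the deposited tables nor the reference marks transposon genes, so a list of these was not tested. Another 8 lists were chosen after the values were seen and are kept apart in the closing observations. Per pairwise comparison, the rule names the 6 largest rises and the 6 largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups. It adds the 2 most changed members of each of the up to 8 lists with the smallest camera p and up to 6 called genes for peroxide, thioredoxin and glutathione enzymes. For the interaction it names the 5 genes with the smallest p in each direction. It always includes URA3, HIS3, LEU2 and MET17, the general transcription genes RPB7 and SPT15, and the stress regulators YAP1, SKN7, MSN2 and MSN4.

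The model was tested on simulated data, drawn from the means and library sizes of these samples with 66 or 67 genes changed at each of 1.5-fold, 2-fold and 4-fold. Of genes changed 2-fold, 85.1% were recovered in the nHP strain comparison, 94.0% in the HP strain comparison, 91.0% and 97.0% for HP against nHP in the control and mutation strain, and 89.6% in the interaction. At 1.5-fold the shares were 77.6%, 82.1%, 76.1%, 77.3% and 44.8%. False calls made up 5.00%, 5.80%, 2.50%, 6.70% and 5.90% of all calls, in the same order. All groups were drawn with 1 mean and 1 spread per gene, apart from the planted changes, which included a gene list. The data depart from this, since replicate spread differed between groups and up to 49.3% of genes were called. These shares may therefore not carry over to the comparisons below.

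Total counts ran from 8296520 to 11202400 per library. A gene with 0 counts could have had up to 3 counts, or 0.268 to 0.362 CPM depending on the library; such floors cover counting error only, since the reads carry no molecular identifiers. Alternatives were RLE size factors, no composition normalization, scaling without the 50 most abundant genes, no filter, a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, limma on log2 RPKM with a pseudocount of 1 or 0.1, a replicate block, only the 4 libraries compared, a 2-fold minimum, and leaving out each library in turn. Named genes were compared with all genes of the reference by BLAST 2.17.0 to find near-identical copies. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out.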

Results

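RNA was sequenced from Saccharomyces cerevisiae BY4741, a haploid laboratory yeast of mating type a. Of the 2 strains, one is called the mutation strain, which the labels describe as having better tolerance of oxidation stress, and the other the control strain. The mutated gene is not given in the sources used here. Each strain has 2 libraries titled HP and 2 titled nHP. The series description says that both strains grew in medium lacking uracil, in the presence or absence of hydrogen peroxide, and were collected in mid-exponential phase. The medium entry of the labels contradicts this, since it assigns peroxide to every control strain library and no peroxide to every mutation strain library. The groups therefore follow the titles, and HP and nHP are used below as titles, without a statement of which cultures held peroxide. If the medium entry were the right one, strain and peroxide would be confounded. Nothing states that the 2 libraries of a group are separate cultures, so the p-values measure only the spread between these samples, which can be technical.

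Total counts were 8893770 and 9089560 for the nHP control libraries, 8296520 and 8850120 for the nHP mutation libraries, 8524140 and 11202400 for the HP control libraries, and 10539200 and 9156260 for the HP mutation libraries, each pair in the order of replicates 1 and 2. LEU2 and MET17, which are deleted in BY4741, had 0 counts in all 8 libraries, where a count of 0 allows at most 0.362 CPM. URA3 and HIS3, also auxotrophic marker genes of BY4741, had 14559 to 38860 and 404 to 958 counts per library. Whether their reads come from a native or an introduced copy was not tested. The 10 most abundant genes held 6.36% to 7.63% of the counts. Replicates differed by more than 1.5-fold in 150 genes in the nHP control group, 220 in the nHP mutation group, 295 in the HP control group and 161 in the HP mutation group. HP control replicate 1 stood apart from replicate 2 in several of the gene groups below. On the first principal component, with 46.5% of the variance, the HP mutation libraries lay at 29.1 and 26.3 and the other 6 between −16.7 and 0.077. On the second, with 33.8%, the nHP mutation libraries lay at −21.2 and −27.5 and the other 6 between 3.77 and 13.6.

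Below, a gene rose or fell when its adjusted p was below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A value after ± is the standard error of a log2 fold change, with 2 libraries per group, unless it is marked as an SD. Adjusted p of lists come from limma's camera test with Benjamini-Hochberg adjustment. Members named as exceptions within a list, and any other genes outside the naming rule, were chosen after their values were seen.

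Among the nHP libraries, where the question is how the strains differ under that title, most genes of mating type a and pheromone response were lower in the mutation strain, and TAF10 was far higher. TAF10 (YDR167W), a subunit of the TFIID and SAGA transcription complexes, rose 122-fold, from 102 ± 14 CPM (SD, n = 2) to 12431 ± 1124 CPM (SD, n = 2). MFA2 (YNL145W) and MFA1 (YDR461W), which encode the a-factor mating pheromone, fell 224-fold and 131-fold, MFA2 from 655 ± 47.7 CPM (SD, n = 2) to 2.92 ± 0.073 CPM (SD, n = 2). The alpha-factor receptor gene STE2 (YFL026W) fell 62.5-fold, the agglutinin subunit gene AGA2 51.7-fold, the pheromone protease gene BAR1 31.9-fold and the mating kinase gene FUS3 16.5-fold. The log2 fold changes were 6.93 ± 0.21 for TAF10 and −7.03 ± 0.17 for MFA1. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 9.26e-10 for TAF10 and 2.53e-10 for MFA1.

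Of 23 measured genes on the list mating type a and pheromone response, 20 fell, 1 rose and 2 did not pass, and 21 were called when adjusted over the list alone. The median log2 fold change was −2.73 (adjusted p = 7.14e-21, and adjusted p = 0.0421 with an estimated correlation). PRM3 was the member that rose, by 0.61 ± 0.19, while PRM8 and PRM10 stood at 0.10 ± 0.13 and −0.08 ± 0.17. Outside this list, HMRA1 fell by 1.16 ± 0.20 on the log2 scale; reads of an a1 gene at the mating type locus would be counted under the same name if the reference carries alpha genes there. The 4 measured markers of mating type alpha were too few to test: SAG1 and STE3 fell by 0.48 ± 0.11 and 1.28 ± 0.27, and MF(ALPHA)1 and MF(ALPHA)2, at −0.33 ± 0.29 and −0.51 ± 0.18, did not pass.

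**Figure D1:**
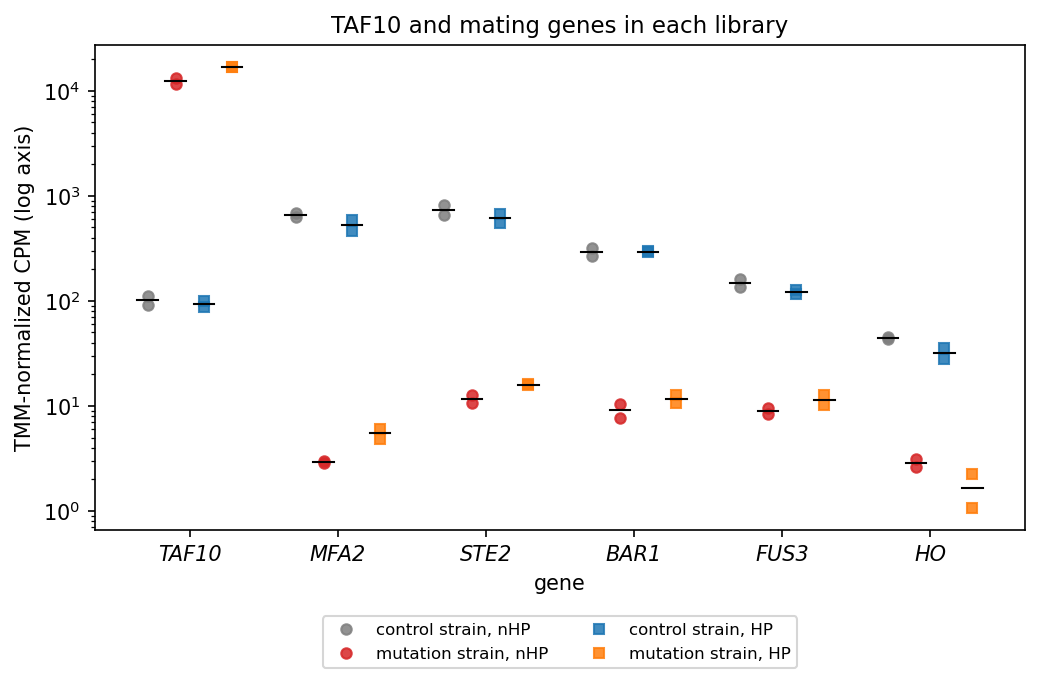
CPM (log axis) of TAF10, MFA2, STE2, BAR1, FUS3 and HO in each of the 8 libraries, with 1 dot per library and a bar at the mean of each group. TAF10 lay near 102 and 92.9 CPM in the nHP and HP control groups and at 12431 and 16687 CPM in the mutation groups, and the other 5 genes were lower in every mutation strain library than in every control strain library.

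Genes for building ribosomes, degrading proteins and folding proteins rose together in the nHP mutation strain libraries. Of 89 genes of ribosome biogenesis, 74 rose, none fell and 15 did not pass, with 81 called when adjusted over the list alone. Their median log2 fold change was 0.55 (adjusted p = 1.33e-25, but adjusted p = 0.684 with an estimated correlation). NOP7, needed for the large ribosomal subunit, rose by 0.98 ± 0.13. Every one of the 34 proteasome genes rose, also when adjusted over the list alone, with a median of 0.53 (adjusted p = 5.64e-19, but adjusted p = 0.526 with an estimated correlation). The regulatory particle genes RPN1 and RPT1 rose by 0.80 ± 0.11 and 0.68 ± 0.10. Of 30 heat shock chaperones, 23 rose, 1 fell and 6 did not pass, with 27 called when adjusted over the list alone and a median of 0.70 (adjusted p = 3.24e-14, but adjusted p = 0.526 with an estimated correlation). BTN2, a factor that sorts misfolded proteins, rose 3.87-fold (1.95 ± 0.11), and the Hsp90 gene HSP82, which shares 91.8% of its sequence with HSC82, rose 2.73-fold. The small chaperone gene HSP26 was the exception and fell by 1.57 ± 0.13. Without nHP control replicate 1 the risers numbered 18 in ribosome biogenesis, 12 in the proteasome and 15 among heat shock chaperones, and without nHP mutation replicate 2 they numbered 25 in ribosome biogenesis and 19 in the proteasome.

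Enzymes that reduce peroxides were among the largest rises. GPX2, a glutathione peroxidase gene, rose 3.23-fold from 63.0 ± 23.7 CPM (SD, n = 2) to 204 ± 2.67 CPM (SD, n = 2), and SRX1, for sulfiredoxin, rose 2.58-fold. The peroxiredoxin gene AHP1 rose by 0.91 ± 0.14, the thioredoxin reductase gene TRR1 by 0.85 ± 0.13 and the glutathione synthesis gene GSH1 by 0.64 ± 0.10. TSA1, the main cytosolic peroxiredoxin gene, rose by 0.87 ± 0.16 but not without nHP control replicate 1 (0.67, adjusted p = 0.0634 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). On the list of peroxide, thioredoxin and glutathione enzymes, 10 of 34 rose, 2 fell (GRX1 and TRR2) and 22 did not pass, with 12 called when adjusted over the list alone. Its median was 0.16 (adjusted p = 0.0305, but adjusted p = 0.893 with an estimated correlation). Among 25 Yap1 targets, of which 11 are on the former list too, 11 rose, none fell and 14 did not pass, with 15 called when adjusted over the list alone and a median of 0.23 (adjusted p = 0.0381, but adjusted p = 0.837 with an estimated correlation). Without nHP control replicate 1, 5 genes rose on each of these lists, and the list calls ended (adjusted p = 0.0706 for peroxide, thioredoxin and glutathione enzymes and 0.0813 for Yap1 targets). They ended too without nHP mutation replicate 1 (0.0695 and 0.0558), and that of Yap1 targets without HP control replicate 1 or 2 (0.0593 and 0.0696). A replicate block ended both list calls (adjusted p = 0.0638 for each). Without nHP mutation replicate 2, 6 of the peroxide, thioredoxin and glutathione enzymes rose.

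Smaller groups moved as well. Of 26 genes of purine and pyrimidine synthesis, 10 rose, 2 fell (FCY2 and MTD1) and 14 did not pass, with 16 called when adjusted over the list alone and a median of 0.28 (adjusted p = 0.0004, but adjusted p = 0.684 with an estimated correlation). GUA1, for GMP synthase, rose by 0.75 ± 0.13. Of 15 genes of arginine metabolism, 8 fell, none rose and 7 did not pass, with 11 called when adjusted over the list alone and a median of −0.50 (adjusted p = 0.00259, but adjusted p = 0.526 with an estimated correlation). The argininosuccinate lyase gene ARG4 fell by 0.97 ± 0.10. Without nHP control replicate 1, 1 of the purine and pyrimidine synthesis genes rose and 5 of arginine metabolism fell, and without nHP mutation replicate 2 the numbers were 3 and 5. HPF1, a cell wall mannoprotein gene, rose 2.82-fold. URA3, the gene selected for in medium without uracil, fell 2.24-fold, from 4072 ± 188 CPM (SD, n = 2) to 1821 ± 28.8 CPM (SD, n = 2). The stress regulator gene YAP1 rose by 0.45 ± 0.09 but not without nHP control replicate 1 (0.46, adjusted p = 0.0591 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HIS3, a histidine synthesis gene, fell by 0.43 ± 0.13, but not without nHP control replicate 2 (−0.22, adjusted p = 0.298 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), nHP mutation replicate 2 (−0.30, 0.279), HP mutation replicate 1 (−0.43, 0.0554) or HP mutation replicate 2 (−0.43, 0.0602). RPB7, SPT15, SKN7, MSN2 and MSN4 did not pass.

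Of 36 genes of meiosis and sporulation, 5 fell, SPO74 rose and 30 did not pass, with 4 called when adjusted over the list alone and a median of −0.21 (adjusted p = 0.0381, but adjusted p = 0.526 with an estimated correlation). The 5 became 1 without nHP control replicate 1, nHP control replicate 2 or nHP mutation replicate 2 and 3 without nHP mutation replicate 1, and the list call ended without nHP control replicate 1 (adjusted p = 0.140), without nHP mutation replicate 2 (0.0936) and with the filter of 10 CPM in 2 libraries (0.282).

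In total 1318 of 6174 genes were called in nHP, 706 higher and 612 lower in the mutation strain, with 27 higher and 120 lower by at least 2-fold. Without nHP control replicate 1, more genes were lower than higher. The count was 418 without nHP control replicate 1, 704 without nHP control replicate 2 and 437 without nHP mutation replicate 2. Without composition normalization the median of all genes shifted by −0.13 and the split was 419 higher and 1236 lower, and on RPKM values with a pseudocount of 1 it was 372 and 1139; the directions of the lists above were kept in both.

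Among the HP libraries, the mutation strain again had lower transcripts of most mating type a genes and higher TAF10, and it also had more transcripts for using carbon sources other than glucose. TAF10 rose 179-fold, to 16687 ± 6.37 CPM (SD, n = 2). MFA2 fell 95.5-fold, MFA1 62.5-fold, STE2 38.3-fold, AGA2 29.5-fold, BAR1 25.3-fold and HO, the endonuclease of mating type switching, 18.8-fold. ADY2 (YCR010C), an acetate transporter gene, rose 7.95-fold, from 47.7 ± 29.9 CPM (SD, n = 2) to 373 ± 39.3 CPM (SD, n = 2). The lactate transporter gene JEN1 rose 6.02-fold. RGI2 rose 10.1-fold, the glycerol transporter gene STL1 8.61-fold and POX1, which starts peroxisomal fatty acid oxidation, 7.60-fold (log2 fold change 2.93 ± 0.32). The HP control libraries varied widely for these genes too. JEN1 stood there at 91.5 ± 48.0 CPM, RGI2 at 37.1 ± 28.7, STL1 at 97.6 ± 63.7 and POX1 at 32.2 ± 19.5 (SD, n = 2 each).

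On the list mating type a and pheromone response, 18 of 23 fell, 2 rose (PRM8 and PRM10) and 3 did not pass (FIG1, PRM2 and PRM3), with 20 called when adjusted over the list alone. Its median was −1.74 (adjusted p = 1.31e-13, but adjusted p = 0.0922 with an estimated correlation). Of the markers of mating type alpha, MF(ALPHA)1 rose by 1.13 ± 0.24, while SAG1, STE3 and MF(ALPHA)2 did not pass.

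Of 20 genes of gluconeogenesis and glyoxylate, 19 rose, also when adjusted over the list alone, and ACH1 did not pass (adjusted p = 0.994 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median was 1.04 (adjusted p = 2.11e-11, but adjusted p = 0.704 with an estimated correlation). The mean level of this list in HP control replicate 1 was −0.023 on the log2 scale relative to all libraries and −0.50 in replicate 2, against 1.02 and 0.91 in the HP mutation libraries. Of 40 genes of the general stress response, 25 rose, 2 fell (DDR48 and YGP1) and 13 did not pass, with 30 called when adjusted over the list alone and a median of 0.52 (adjusted p = 1.08e-06, but adjusted p = 0.704 with an estimated correlation). GRE1 and SIP18, genes induced by osmotic stress and drying, rose 5.76-fold and 3.85-fold. The mean level of the general stress response was 0.14 in HP control replicate 1 and −0.31 in replicate 2. Of 30 iron regulon genes, 17 rose, none fell and 13 did not pass, with 17 called when adjusted over the list alone and a median of 0.32 (adjusted p = 5.05e-06, but adjusted p = 0.704 with an estimated correlation). FIT2, a cell wall mannoprotein that holds iron siderophores, rose 3.11-fold and the siderophore transporter gene SIT1 2.59-fold. Of 27 autophagy genes, 14 rose, 1 fell (ATG13) and 12 did not pass, with 17 called when adjusted over the list alone and a median of 0.40 (adjusted p = 8.23e-06, but adjusted p = 0.704 with an estimated correlation). ATG39, a receptor gene for autophagy of the nucleus, rose by 1.20 ± 0.13 and the scaffold gene ATG11 by 0.92 ± 0.12. Without HP mutation replicate 1 the risers numbered 12 in the general stress response, 11 in the iron regulon and 8 in autophagy, and without HP control replicate 2 the general stress response had 15.

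Lists of growth genes fell in the HP strain comparison, beside mating type a and the lists given further below. Of 89 genes of ribosome biogenesis, 48 fell, none rose and 41 did not pass, with 71 called when adjusted over the list alone and a median of −0.36 (adjusted p = 1.68e-10, but adjusted p = 0.704 with an estimated correlation). UTP10, of the small subunit processome, fell by 0.62 ± 0.12 but not without HP mutation replicate 1 (−0.54, adjusted p = 0.064 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The count of 48 was 79 without HP control replicate 1, 3 without HP control replicate 2, 1 without HP mutation replicate 1, 11 without HP mutation replicate 2, 25 without nHP control replicate 1 and 24 without nHP control replicate 2, and the mean level of ribosome biogenesis was −0.20 in HP control replicate 1 and 0.12 in replicate 2. Of 136 cytosolic ribosomal proteins, 8 fell and 128 did not pass, with a median of −0.27 (adjusted p = 1.25e-07, but adjusted p = 0.704 with an estimated correlation). None was called when adjusted over the list alone, 51 had an unadjusted p under 0.05, and DESeq2 called 12 and limma-voom 8. For these cytosolic ribosomal proteins the 8 became 80 without HP control replicate 1 and 0 without HP control replicate 2 or HP mutation replicate 1, and 3 without HP mutation replicate 2 or either nHP control replicate. Of 24 genes of glycolysis and fermentation, 10 fell, PDC6 rose and 13 did not pass, with 18 called when adjusted over the list alone and a median of −0.41 (adjusted p = 0.000238, but adjusted p = 0.704 with an estimated correlation). None of these glycolysis and fermentation genes fell without HP mutation replicate 1, 3 did without HP mutation replicate 2, 4 without HP control replicate 2, and 6 and 5 without nHP control replicates 1 and 2.

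Other lists fell in the HP strain comparison as well. Of 31 sulfur and methionine genes, 14 fell, 3 rose (MET30, STR2 and MET2) and 14 did not pass, with 19 called when adjusted over the list alone and a median of −0.28 (adjusted p = 0.00924, but adjusted p = 0.704 with an estimated correlation). Of the 14, 3 fell without HP control replicate 2, 8 without HP mutation replicate 1, 2 without HP mutation replicate 2, 6 without either nHP control replicate and 7 without either nHP mutation replicate, and the call of sulfur and methionine ended without HP control replicate 2 (adjusted p = 0.0517) or HP mutation replicate 2 (0.207). Of 11 histones, HTB2, HTA2 and HHF1 fell and 8 did not pass, with 5 called when adjusted over the list alone and a median of −0.24 (adjusted p = 0.0116, but adjusted p = 0.704 with an estimated correlation). The 3 histones became 6 without HP control replicate 1, 1 without HP control replicate 2 (where the list call ended, adjusted p = 0.0517), 0 without HP mutation replicate 1 and 1 without HP mutation replicate 2. Of 51 genes of amino acid biosynthesis (Gcn4 targets), 16 fell, 7 rose and 28 did not pass, with 26 called when adjusted over the list alone and a median of −0.18 (adjusted p = 0.0424, but adjusted p = 0.704 with an estimated correlation). For amino acid biosynthesis (Gcn4 targets) the 16 became 8 and 7 without nHP control replicates 1 and 2, 4 without HP control replicate 2, and 1 and 5 without HP mutation replicates 1 and 2. This list call ended without each of these libraries (adjusted p = 0.0501, 0.0508, 0.0787, 0.0501 and 0.0872), without HP control replicate 1 (0.0630) and with the filter of 10 CPM (0.0552).

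**Figure D2:**
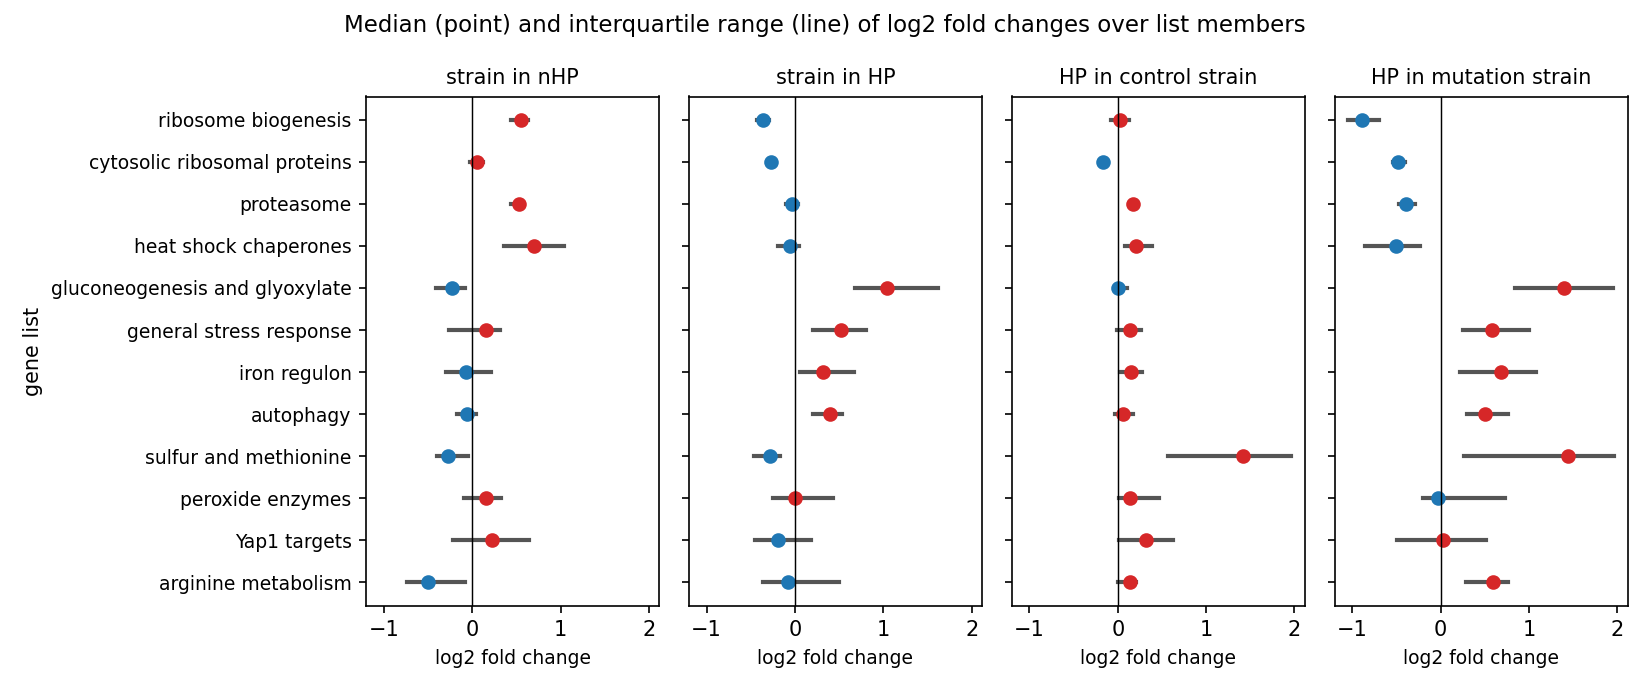
Median log2 fold change (points) and interquartile range (lines) of the members of 12 gene lists in the 4 pairwise comparisons. Ribosome biogenesis genes had medians of 0.55 and −0.36 in the nHP and HP strain comparisons. Sulfur and methionine genes had medians of 1.42 and 1.44 for HP against nHP in the control and mutation strain.

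The peroxide, thioredoxin and glutathione enzymes split in HP: 11 of 34 rose, 6 fell and 17 did not pass, with 19 called when adjusted over the list alone. Their mean was 0.10 and the list did not pass (adjusted p = 0.344). The peroxisomal catalase gene CTA1 rose 4.66-fold, from 71.0 ± 32.4 CPM (SD, n = 2) to 328 ± 48.2 CPM (SD, n = 2). The glutathione transferase gene GTT1 rose by 0.81 ± 0.10 and the mitochondrial peroxiredoxin gene PRX1 by 0.73 ± 0.11. GPX2 fell 2.22-fold, from 185 ± 51.3 CPM (SD, n = 2) to 83.6 ± 5.05 CPM (SD, n = 2). URA3, at −0.06 ± 0.13, did not pass, nor did HIS3, YAP1, RPB7, SPT15, SKN7, MSN2 or MSN4.

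In HP, 1769 genes were called, 907 higher and 862 lower in the mutation strain, with 153 higher and 93 lower by at least 2-fold. This split was 986 and 722 with RLE size factors, 1048 and 611 with the filter of 10 CPM, 700 and 342 with only the 4 libraries compared, 1099 and 1251 with the replicate block, and 455 and 206 without HP mutation replicate 1. The count was 1014 without HP control replicate 2, 661 without HP mutation replicate 1 and 883 without HP mutation replicate 2. The strain differences of nHP and HP shared 255 genes called in the same direction, 59 higher and 196 lower, where 104 and 85.4 would be expected if the calls were independent, and 228 genes were called in opposite directions. The model's 1 spread per gene enters both comparisons, so the calls are not independent and these expected numbers are only a rough mark. Across genes, which are not independent replicates, the fold changes had r = 0.382 and rho = −0.041. The 255 became 137 without either nHP control replicate, 155 and 145 without nHP mutation replicates 1 and 2, 393 without HP control replicate 1, and 134 and 160 without HP mutation replicates 1 and 2.

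In the control strain, sulfur metabolism genes had the largest rises from nHP to HP libraries, and single genes of zinc and copper uptake were among the largest falls. STR3 (YGL184C), a cystathionine lyase gene, rose 9.95-fold, from 12.1 ± 1.92 CPM (SD, n = 2) to 120 ± 15.3 CPM (SD, n = 2). MHT1 and MMP1, a methyltransferase and a permease for S-methylmethionine, rose 6.69-fold and 4.80-fold, and the sulfate assimilation genes MET3, MET14 and MET5 rose 5.58-fold, 5.19-fold and 4.84-fold. ZRT1 (YGL255W), the high-affinity zinc transporter gene, fell 9.15-fold, from 1288 ± 163 CPM (SD, n = 2) to 141 ± 18.1 CPM (SD, n = 2). ZPS1, another gene induced by low zinc, fell 7.39-fold, the copper transporter gene CTR1 5.38-fold and the metal reductase gene FRE1 2.45-fold. ANB1, a translation factor gene made under low oxygen that shares 91.1% of its sequence with HYP2, fell 2.11-fold.

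Of 31 genes of the list sulfur and methionine, 25 rose, none fell and 6 did not pass, with 26 called when adjusted over the list alone. The median log2 fold change was 1.42 (adjusted p = 3.83e-43, but adjusted p = 0.282 with an estimated correlation). The methionine sulfoxide reductase gene MXR1, which repairs oxidized methionine, rose 4.08-fold (2.03 ± 0.13). GPX2 rose 2.95-fold and BTN2 2.55-fold. These rises and those in the nHP strain comparison use the same nHP control libraries. Relative to all libraries, the mean log2 level of Yap1 targets was −0.33 and −0.18 there and 0.003 to 0.17 in the other libraries. For peroxide, thioredoxin and glutathione enzymes it was −0.30 and −0.18 against −0.039 to 0.26. SRX1 and GSH1 rose by 1.33 ± 0.20 and 0.62 ± 0.10 but neither was called without nHP control replicate 1 (1.03 and 0.52, adjusted p = 0.0523 and 0.168 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 34 peroxide, thioredoxin and glutathione enzymes, 6 rose, none fell and 28 did not pass, with 11 called when adjusted over the list alone, a median of 0.13 (adjusted p = 1.51e-06, but adjusted p = 0.524 with an estimated correlation) and 2 risers without nHP control replicate 1. Of 25 Yap1 targets, 6 rose and 19 did not pass, with 13 called when adjusted over the list alone, a median of 0.33 (adjusted p = 3.79e-08, but adjusted p = 0.282 with an estimated correlation) and 1 riser without nHP control replicate 1.

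Other lists passed in the control strain with small medians and few called members. Of 30 heat shock chaperones, BTN2, HSP78, SSA4 and FES1 rose and 26 did not pass, with 6 called when adjusted over the list alone, a median of 0.21 (adjusted p = 8.04e-09, but adjusted p = 0.524 with an estimated correlation) and 1 riser without either nHP control replicate. Of 23 genes of the list mating type a and pheromone response, MFA1, FIG1, AGA1 and AGA2 fell and 19 did not pass, with 5 called when adjusted over the list alone and a median of −0.21 (adjusted p = 0.000138, but adjusted p = 0.282 with an estimated correlation). These 4 became 2 and 0 without nHP control replicates 1 and 2 and 7 without HP control replicate 2. No cytosolic ribosomal protein or proteasome gene was called by edgeR, DESeq2 or limma-voom, with 6 of 136 and 8 of 34 at an unadjusted p under 0.05. Their medians were −0.16 (adjusted p = 1.12e-10, but adjusted p = 0.767 with an estimated correlation) and 0.17 (adjusted p = 2.03e-08, but adjusted p = 0.590 with an estimated correlation). Without HP control replicate 1 the test of cytosolic ribosomal proteins gave adjusted p = 0.450. The general stress response had 2 risers in 40, TMA10 and DDR48, with 2 called when adjusted over the list alone, and a median of 0.14 (adjusted p = 0.00608, but adjusted p = 0.773 with an estimated correlation), which became −0.08 (adjusted p = 0.178) without HP control replicate 1. The call ended too without nHP control replicate 2 (adjusted p = 0.0854). Of 30 iron regulon genes, VHT1 and FET3 rose, FRE1 fell and 27 did not pass, with 3 called when adjusted over the list alone and a median of 0.15 (adjusted p = 0.00232, but adjusted p = 0.715 with an estimated correlation). The 2 risers of the iron regulon became 1 without either nHP control replicate and 4 without HP control replicate 2, and 2 of its genes fell without HP control replicate 1, where the list call ended (adjusted p = 0.210).

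The control strain had 121 called genes, 89 higher and 32 lower in HP, with 33 and 9 by at least 2-fold, and 721 genes at an unadjusted p under 0.05. The count was 51 and 54 without nHP control replicates 1 and 2, and 218 and 206 without HP control replicates 1 and 2. Of the 29 lists, 12 passed with the preset correlation and 0 with an estimated correlation, and 20 did without HP control replicate 2.

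In the mutation strain, HP libraries shared the rise in sulfur genes and differed in a far wider set of genes, those for growth being lower and those for other carbon sources higher. RGI2 (YIL057C) rose 15-fold, from 24.4 ± 18.1 CPM (SD, n = 2) to 366 ± 52.0 CPM (SD, n = 2), STR3 11.3-fold, MHT1 11.1-fold and MMP1 6.46-fold. ADY2 rose 8.31-fold and POX1 7.44-fold. ZRT1 fell 3.27-fold and CTR1 3.06-fold. Genes for growth fell next: RNR1, for the large subunit of ribonucleotide reductase, by 1.36 ± 0.15, REA1 and SDA1, which act in ribosome assembly, by 1.36 ± 0.11 and 1.36 ± 0.12, and HRP1, an RNA processing factor, by 1.35 ± 0.13.

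Of 89 genes of ribosome biogenesis, 85 fell and 4 did not pass (BUD23, RPA14, UTP30 and RRP9), with 87 called when adjusted over the list alone. The median was −0.89 (adjusted p = 5.54e-25, but adjusted p = 0.438 with an estimated correlation). NOP7 and KRR1, of the large and small subunit pathways, fell 2.53-fold and by 1.31 ± 0.11 on the log2 scale. Of 136 cytosolic ribosomal proteins, 118 fell, none rose and 18 did not pass, with 127 called when adjusted over the list alone and a median of −0.48 (adjusted p = 1.11e-14, but adjusted p = 0.473 with an estimated correlation). RPL13A and RPL12A, which share 93.0% and 91.9% of their sequence with their B copies, fell by 0.72 ± 0.12 and 0.69 ± 0.13. The 118 became 22 without nHP mutation replicate 2 and 14 without HP mutation replicate 1, and 85 fell and 2 rose among cytosolic ribosomal proteins without composition normalization. Of 34 proteasome genes, 28 fell, 1 rose and 5 did not pass, with 33 called when adjusted over the list alone and a median of −0.39 (adjusted p = 5.27e-08, but adjusted p = 0.438 with an estimated correlation). RPN1 and PRE1 fell by 0.74 ± 0.11 and 0.59 ± 0.09, and RPN4, the transcription factor of proteasome genes, rose by 0.52 ± 0.10. The 28 in the proteasome became 13 without nHP mutation replicate 2 and 15 without HP mutation replicate 2. Of 30 heat shock chaperones, 22 fell, 3 rose (SSA3, HSP26 and HSP33) and 5 did not pass, with 25 called when adjusted over the list alone and a median of −0.50 (adjusted p = 3.9e-06, but adjusted p = 0.438 with an estimated correlation). The Hsp40 gene YDJ1 fell 2.35-fold and CUR1, which sorts misfolded proteins, 2.15-fold. In the HP strain comparison, 33 of the 34 proteasome genes and 25 of the 30 heat shock chaperones did not pass. Their medians there were −0.04 and −0.06. The fall of these lists here and their rise in the nHP strain comparison use the same nHP mutation libraries. Of 26 genes of purine and pyrimidine synthesis, 19 fell, 4 rose (FCY2, URA8, MTD1 and URA10) and 3 did not pass, with 23 called when adjusted over the list alone and a median of −0.50 (adjusted p = 0.000714, but adjusted p = 0.438 with an estimated correlation). Of 11 histones, 9 fell and 2 did not pass (CSE4 and HTZ1), with 9 called when adjusted over the list alone and a median of −0.52 (adjusted p = 0.00104, but adjusted p = 0.453 with an estimated correlation).

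**Figure D3:**
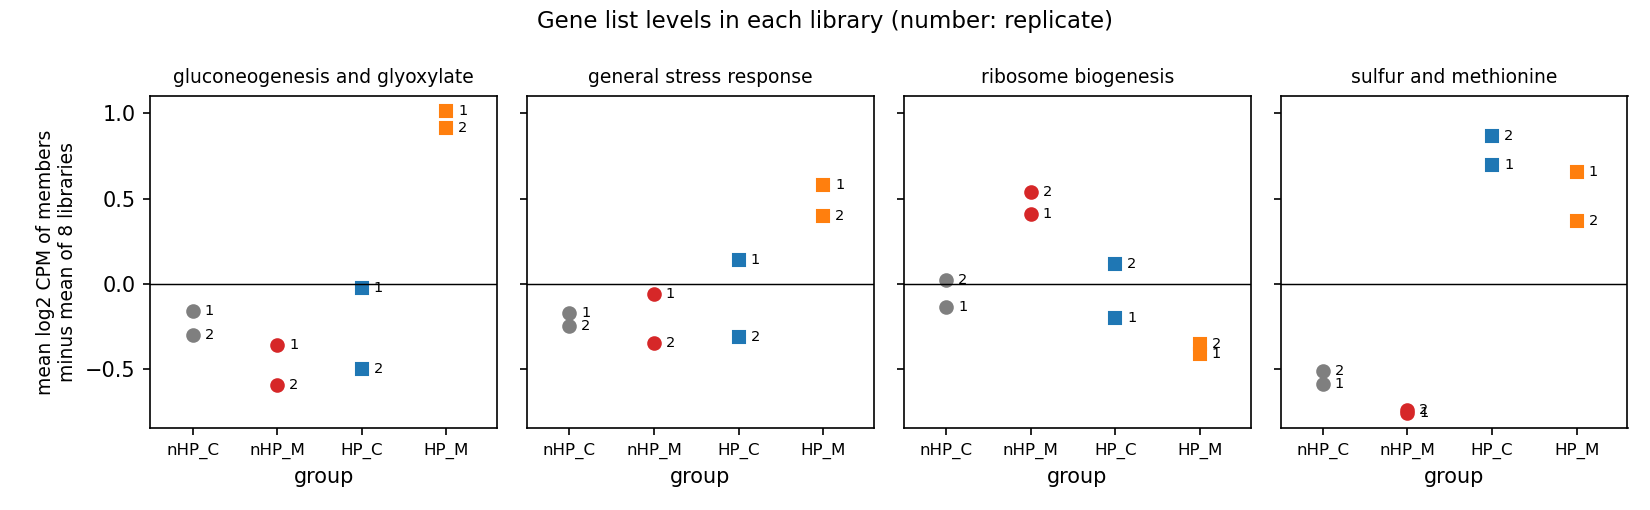
Mean log2 CPM of the members of 4 gene lists in each library, minus the mean over the 8 libraries, with 1 dot per library. Gluconeogenesis stood at 1.02 and 0.91 in the HP mutation libraries, and at −0.023 and −0.50 in HP control replicates 1 and 2.

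Among the lists that rose, 19 of 20 genes of gluconeogenesis and glyoxylate passed, also when adjusted over the list alone, and MDH2 did not. Their median was 1.39 (adjusted p = 6.43e-09, but adjusted p = 0.438 with an estimated correlation), and JEN1 rose 4.77-fold. Of 31 sulfur and methionine genes, 23 rose, HOM6 fell and 7 did not pass, with 24 called when adjusted over the list alone and a median of 1.44 (adjusted p = 7.25e-09, but adjusted p = 0.438 with an estimated correlation). Of 30 iron regulon genes, 22 rose, FRE1 fell and 7 did not pass, with 23 called when adjusted over the list alone and a median of 0.69 (adjusted p = 3.9e-06, but adjusted p = 0.438 with an estimated correlation). TIS11, an mRNA-binding protein made under low iron, rose 3.75-fold and FIT3, a siderophore-holding mannoprotein, 2.52-fold. Of 40 genes of the general stress response, 25 rose, none fell and 15 did not pass, with 27 called when adjusted over the list alone and a median of 0.58 (adjusted p = 7.05e-06, but adjusted p = 0.513 with an estimated correlation). GRE1 and SIP18 rose 5.86-fold and 5.64-fold. Of 27 autophagy genes, 19 rose and 8 did not pass, with 19 called when adjusted over the list alone and a median of 0.50 (adjusted p = 7.7e-06, but adjusted p = 0.438 with an estimated correlation). Of 15 genes of arginine metabolism, 10 rose and 5 did not pass, with 11 called when adjusted over the list alone and a median of 0.59 (adjusted p = 0.000425, but adjusted p = 0.438 with an estimated correlation). Of 40 genes of the respiratory chain and ATP synthase, 18 rose and 22 did not pass, with 18 called when adjusted over the list alone and a median of 0.24 (adjusted p = 0.000442, but adjusted p = 0.438 with an estimated correlation).

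The peroxide, thioredoxin and glutathione enzymes again split: 14 of 34 rose, 6 fell and 14 did not pass, with 20 called when adjusted over the list alone. The median was −0.025 and the mean 0.19, and the list did not pass (adjusted p = 0.396, with the mean's sign); the median was 0.10 without composition normalization. CTA1 rose 4.94-fold, MXR1 3.02-fold, ECM4 by 0.94 ± 0.12 and GTT1 by 0.92 ± 0.10, the last pair being glutathione transferase genes. GPX2 fell 2.43-fold and AHP1 fell by 0.95 ± 0.14. URA3 rose by 0.85 ± 0.13, to 3287 ± 239 CPM (SD, n = 2). HIS3 rose by 0.40 ± 0.13, but not without nHP mutation replicate 2 (0.28, adjusted p = 0.182 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), HP mutation replicate 1 (0.44, 0.0665) or HP mutation replicate 2 (0.38, 0.103). SPT15, the TATA-binding protein gene, fell by 0.32 ± 0.11, but not without nHP mutation replicate 1 (−0.26, adjusted p = 0.152 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), nHP mutation replicate 2 (−0.36, 0.0693) or HP mutation replicate 2 (−0.24, 0.180).

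**Figure D4:**
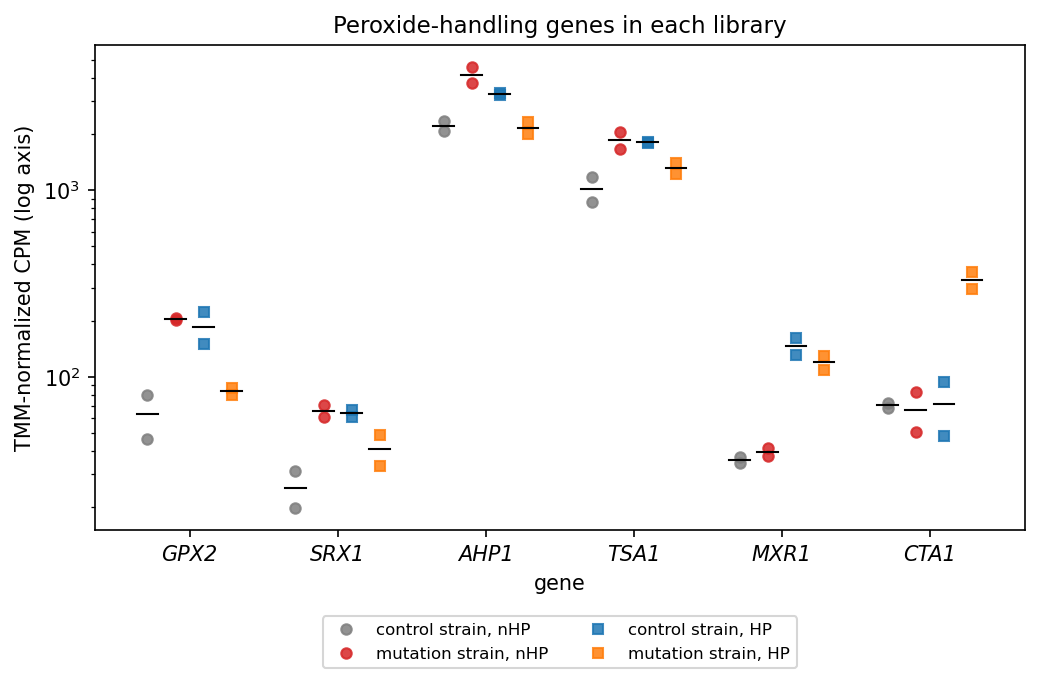
CPM (log axis) of GPX2, SRX1, AHP1, TSA1, MXR1 and CTA1 in each of the 8 libraries, with 1 dot per library and a bar at the group mean. GPX2 averaged 63.0 and 185 CPM in the nHP and HP control libraries and 204 and 83.6 CPM in the nHP and HP mutation libraries.

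The mutation strain had 3043 called genes, 1557 higher and 1486 lower in HP, with 266 and 101 by at least 2-fold. The count was 1773 without nHP mutation replicate 2 and 1997 without HP mutation replicate 1. Without composition normalization the median of all genes shifted by 0.12 and the split was 2106 higher and 1051 lower, and on RPKM values with a pseudocount of 1 it was 2061 and 988; the lists named above kept their directions in both, the peroxide, thioredoxin and glutathione enzymes excepted. The HP differences of the control and mutation strain shared 71 genes called in the same direction, 58 higher and 13 lower, where 22.4 and 7.70 would be expected if the calls were independent, and 13 genes were called in opposite directions. Here too the model's 1 spread per gene enters both sets of calls, so the expected numbers are only a rough mark. Of the 121 genes called in the control strain, 88 had the same sign in the mutation strain. Across genes r was 0.234 and rho 0.154. The 71 became 38 without either nHP control replicate and 141 without HP control replicate 2.

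The interaction asks whether the HP difference itself depended on the strain, and it did for genes of protein folding, ribosome building and the use of other carbon sources, and for single genes of peroxide reduction in both directions. GPX2 had an interaction of −2.84 ± 0.31, since it was 2.95-fold higher in HP in the control strain and 2.43-fold lower in the mutation strain (adjusted p = 0.000472 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). SRX1, AHP1, TRR1 and TSA1 followed with −2.0 ± 0.28, −1.52 ± 0.20, −1.33 ± 0.19 and −1.32 ± 0.22. CTA1 went the other way, at 2.30 ± 0.38, and MXR1, at −0.43 ± 0.18, did not pass. BTN2 had the smallest p, at −2.36 ± 0.16: it went from 315 ± 4.66 to 805 ± 11.7 CPM (SD, n = 2 each) in the control strain and from 1221 ± 120 to 609 ± 60.6 CPM (SD, n = 2 each) in the mutation strain.

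Of 89 genes of ribosome biogenesis, 83 had a negative interaction and 6 did not pass, with 86 called when adjusted over the list alone and a median of −0.94 (adjusted p = 2.65e-27, but adjusted p = 0.573 with an estimated correlation). For 34 proteasome genes the numbers were 30 negative and 4 not passing, with 33 called when adjusted over the list alone and a median of −0.56 (adjusted p = 7.66e-12, but adjusted p = 0.573 with an estimated correlation). The 30 of the proteasome became 5 without nHP control replicate 1, 11 without nHP mutation replicate 2, 18 without HP mutation replicate 1 and 15 without HP mutation replicate 2. Of 30 heat shock chaperones, 22 were negative, 2 positive (SSA3 and HSP26) and 6 did not pass, with 26 called when adjusted over the list alone and a median of −0.83 (adjusted p = 9.27e-10, but adjusted p = 0.573 with an estimated correlation). FES1, a nucleotide exchange factor of Hsp70, stood at −1.30 ± 0.13 and YDJ1 at −1.31 ± 0.18. ZPR1, ECM29 and ERO1, which act in folding of a translation factor, on the proteasome and in disulfide formation, had interactions of −1.64 ± 0.15, −1.27 ± 0.13 and −1.14 ± 0.12. Of 20 genes of gluconeogenesis and glyoxylate, 18 were positive and MDH2 and MDH3 did not pass, with 19 called when adjusted over the list alone and a median of 1.31 (adjusted p = 9.27e-10, but adjusted p = 0.573 with an estimated correlation). RGI2 stood at 3.84 ± 0.68, JEN1 at 2.69 ± 0.39, the peroxisomal isocitrate dehydrogenase gene IDP3 at 2.0 ± 0.19 and ADH2, for the alcohol dehydrogenase that uses ethanol and shares 88.8% of its sequence with ADH1, at 2.02 ± 0.19. GPG1 and the glucose-regulated repressor gene NRG2 stood at 1.51 ± 0.14 and 1.62 ± 0.16. For sulfur and methionine the list did not pass (adjusted p = 0.522), with 4 of 31 members positive and 5 negative, 12 called when adjusted over the list alone, and STR3 at 0.19 ± 0.39. ZPS1 stood at 3.42 ± 0.29 and ZRT1 at 1.48 ± 0.19. ZPS1 averaged 134 ± 43.3 CPM (SD, n = 2) in the nHP control libraries and 18.1 to 27.5 CPM in the other groups.

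More lists passed in the interaction. On the list mating type a and pheromone response, 12 of 23 were positive, 2 negative (STE12 and PRM3) and 9 did not pass. With adjustment over the list alone 15 were called, and the median was 0.71 (adjusted p = 0.00146, but adjusted p = 0.573 with an estimated correlation). Several members were low in the mutation strain, where small residual levels enter the log2 values. MFA1 averaged 586 and 362 CPM in the nHP and HP control groups and 4.47 and 5.82 CPM in the mutation groups. For AGA2 these were 116 and 76.2 CPM against 2.24 and 2.53 CPM. The 12 became 6 without nHP mutation replicate 2 and 7 without HP mutation replicate 1. Of 26 genes of purine and pyrimidine synthesis, 17 were negative, 2 positive (FCY2 and URA10) and 7 did not pass, with 20 called when adjusted over the list alone and a median of −0.54 (adjusted p = 0.000211, but adjusted p = 0.573 with an estimated correlation). The 17 of purine and pyrimidine synthesis became 6 without nHP control replicate 1, 7 without nHP mutation replicate 2 or HP mutation replicate 1, and 11 without HP mutation replicate 2. Of 30 iron regulon genes, 18 were positive and 12 did not pass, with 21 called when adjusted over the list alone and a median of 0.53 (adjusted p = 0.000113, but adjusted p = 0.585 with an estimated correlation). The 18 of the iron regulon became 9 without nHP control replicate 1, 7 without nHP mutation replicate 2 and 11 without HP mutation replicate 1. No cytosolic ribosomal protein gene was called by edgeR or limma-voom, against 6 by DESeq2 and 18 at an unadjusted p under 0.05. The list of cytosolic ribosomal proteins had a median of −0.31 (adjusted p = 6.26e-07, but adjusted p = 0.626 with an estimated correlation), and 58 of them were called without HP control replicate 1. The peroxide, thioredoxin and glutathione enzymes, with 9 positive, 9 negative and 16 not passing, 19 called when adjusted over the list alone, did not pass as a list (adjusted p = 0.50).

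The interaction called 1803 genes, 904 positive and 899 negative, and 208 and 100 with at least a 2-fold size. By DESeq2 the split turned to 725 positive and 837 negative, and with the replicate block to 1096 and 1202. Negative genes outnumbered positive ones too without nHP mutation replicate 2 or HP mutation replicate 2. The count was 872 without nHP control replicate 1, 724 without nHP mutation replicate 2, and 953 and 1112 without HP mutation replicates 1 and 2. Without composition normalization the median of all genes shifted by 0.15 and the split was 1321 and 576. On RPKM values with a pseudocount of 1 it was 1208 and 503. The medians of the lists called above kept their directions in both. This leaves out sulfur and methionine and the peroxide, thioredoxin and glutathione enzymes, which were not called.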

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

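Tests of the explanations weighed here were chosen only after the results were seen, while the interaction was planned. What singled out the results below was a difference between the strains in how HP and nHP libraries differed, tested by the interaction in edgeR.

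The interaction called 1803 genes, and 15 lists with the preset correlation but 0 with an estimated correlation. By the rule for named genes, the positive values were 3.42 for ZPS1, 1.51 for GPG1, 2.02 for ADH2, 2.0 for IDP3, 1.62 for NRG2 and 1.10 for URA3. The negative values were −2.36 for BTN2, −1.64 for ZPR1, −1.30 for FES1, −1.27 for ECM29 and −1.14 for ERO1. The count of 1803 was 872 without nHP control replicate 1, 724 without nHP mutation replicate 2, 953 without HP mutation replicate 1 and 1112 without HP mutation replicate 2.

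HP and nHP libraries differed more widely in the mutation strain than in the control strain, with many growth genes lower and genes for other carbon sources higher. Of all genes, the interaction called 29.2%. That share cannot decide whether noisier control strain replicates alone explain the difference. The model estimates 1 spread per gene from all 4 groups, so noise in 1 group need not leave few genes in the interaction. The shared spread also gives both HP comparisons standard errors of like size. For the always-named genes measured, these ran from 0.08 to 0.13 in either strain. That argues against noisier control strain replicates alone as the reason for 121 called genes in the control strain against 3043 in the mutation strain. A later growth stage of the HP mutation strain libraries stays open as a candidate explanation: gluconeogenesis and glyoxylate genes had a median interaction of 1.31 and ribosome biogenesis genes of −0.94, the directions such a stage would give. It would not account for the part that lies in the nHP libraries, where the strains already differed by 0.55 in ribosome biogenesis against −0.36 in HP, and the labels state mid-exponential phase for every library. A difference between the strains in their response to the medium also stays open and was not tested.

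Of 34 peroxide, thioredoxin and glutathione enzymes, 14 rose from nHP to HP in the mutation strain, CTA1 and MXR1 among them, and 6 fell. GPX2, SRX1 and AHP1 were lower in HP than in nHP libraries in the mutation strain, while GPX2 and SRX1 were higher in HP in the control strain (SRX1 not past its threshold there without nHP control replicate 1, at 1.03). Exchanged HP and nHP titles in the mutation strain would turn the other HP differences around as well. The tables argue against that, since the sulfur and methionine genes were higher in HP in the mutation strain, with a median of 1.44, as in the control strain, with 1.42. A difference between the strains in their response to peroxide stays open for the genes that fell, and so does a medium that differs from the titles, on which the labels contradict each other; neither was tested.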

How the results depend on the processing

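All alternatives were planned, and none was chosen after the results were seen. No named gene or called list was called in the opposite direction under the alternatives run for it, which for list tests and overlaps left out no composition normalization, scaling without the 50 most abundant genes, no filter, DESeq2, limma-voom and RPKM. Only the medians of lists, not their tests, were computed without composition normalization and on RPKM with a pseudocount of 1. The balance of higher and lower genes did change sides, as given above for nHP without composition normalization and on RPKM. HP in the mutation strain had 1330 higher and 1403 lower by DESeq2, and the strain in HP 1099 and 1251 with the replicate block. For the interaction, 725 were positive and 837 negative by DESeq2, and 1096 and 1202 with the replicate block. The balance also turned for the strain in nHP without nHP control replicate 1, and for the interaction without nHP or HP mutation replicate 2.

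With a 2-fold minimum the counts of genes were 147 and 246 for the strain in nHP and HP, 42 and 367 for HP in the control and mutation strain, and 308 for the interaction, and the overlaps were 73 for the strain differences and 28 for the HP differences; fewer genes can pass by construction. With only the 4 libraries compared, on fewer residual degrees of freedom, 1042 genes were called for the strain in HP and 72 for HP in the control strain. The counts were higher than in the full model for the strain in nHP, at 1736, and for HP in the mutation strain, at 3426. With a replicate block, which the labels do not ask for, 220 genes were called for HP in the control strain and the overlap of the HP differences was 123. Deviations from the group means correlated between groups by replicate number at −0.033 to 0.204, and at 0.195 for the nHP and HP control libraries, a shared part that the block removes; whether it is why the counts rose was not tested. With the correlation between genes estimated from the data, 1 list was called for the strain in nHP (mating type a and pheromone response) and 0 in each of the other 4 comparisons, where the preset correlation had called 9, 12, 12, 17 and 15.

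Leaving out 1 library left a lone sample in its group, which was assumed to vary like the other groups. For each gene the model estimates 1 spread from all groups, so a group's spread also enters comparisons that do not use it. The HP control pair had the widest spread, with 295 genes over 1.5-fold apart. Leaving out either of its libraries takes that spread out of the estimate. Counts then ran from 418 to 1860 for the strain in nHP, 661 to 2495 for the strain in HP, 51 to 218 for HP in the control strain, 1773 to 3466 for HP in the mutation strain and 724 to 2554 for the interaction. Lists called for HP in the control strain ran from 11 to 20. The overlaps ran from 134 to 393 for the strain differences and from 38 to 141 for the HP differences. The highest count of genes in each comparison, and the highest overlap of the strain differences, came without HP control replicate 1. The 20 lists and the overlap of 141 came without HP control replicate 2, and the cause was not tested.

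Of 127 called values of named genes, 126 kept call and direction with RLE size factors, 126 without composition normalization, 126 with DESeq2 and 126 with limma-voom. On log2 RPKM 121 did with a pseudocount of 1 and 120 with 0.1. With scaling that left out the 50 most abundant genes and with the replicate block all 127 did. Without single libraries the number ran from 112 (nHP control replicate 1) to 127 (HP control replicate 1), and none reversed. Depth limits genes near the floor of 0.268 to 0.362 CPM, below which a count of 0 says nothing.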

Other observations

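The lists in this part and the tests of explanations were chosen only after the results were seen. The genes that only haploid a cells or haploid cells express fell as a whole in the mutation strain. All 7 a-specific genes fell in both strain comparisons, with medians of −5.69 in nHP and −4.88 in HP (adjusted p = 1.15e-14 and 8.41e-13 in limma's camera test with Benjamini-Hochberg adjustment, and 0.0288 and 0.034 with an estimated correlation). All 7 haploid-specific genes of the pheromone pathway fell too, with medians of −2.99 and −3.33, among them the G protein genes GPA1 (−3.63 ± 0.13 in nHP) and STE4 (−3.47 ± 0.10 in nHP). So did all 5 haploid-specific genes outside the pheromone pathway: HO (−3.94 ± 0.23 in nHP), the meiosis repressor gene RME1 (−2.55 ± 0.14), the bud site gene AXL1 (−2.34 ± 0.10), the DNA end-joining gene NEJ1 (−2.02 ± 0.17) and AMN1 (−1.47 ± 0.14).

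Peroxisomes and metals moved as well. Of 16 genes of peroxisomal fatty acid oxidation, 15 rose in the HP strain comparison and ANT1 did not pass, with 15 called when adjusted over the list alone and a median of 1.47 (adjusted p = 3.61e-11, but adjusted p = 0.147 with an estimated correlation). POT1, PXA1, FAA2 and FOX2 rose by 2.55 ± 0.35, 2.32 ± 0.27, 2.08 ± 0.26 and 2.04 ± 0.28. In the control strain no gene of peroxisomal fatty acid oxidation was called for HP against nHP by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05, but 2 fell without HP control replicate 1. The interaction was positive for 14 of the 16, with 16 called when adjusted over the list alone and a median of 1.89 (adjusted p = 5.31e-08, but adjusted p = 0.215 with an estimated correlation). Of 14 genes of the zinc regulon (Zap1 targets), 8 fell in the nHP strain comparison, ZRT2 rose (a call that ended without any 1 of the nHP or HP mutation libraries) and 5 did not pass, with 10 called when adjusted over the list alone and a median of −0.61 (adjusted p = 0.000877, but adjusted p = 0.115 with an estimated correlation). ZPS1, ZRT1, FET4 and the zinc regulator gene ZAP1 fell by 2.82 ± 0.20, 1.57 ± 0.13, 1.31 ± 0.13 and 0.70 ± 0.10. The mean level of the zinc regulon, on the log2 scale relative to all libraries, was 0.47 and 0.59 in the nHP control libraries. In the other libraries it ran from −0.22 to −0.12. This fall and the fall given next use the same nHP control libraries. From nHP to HP in the control strain, 6 of the 14 of the zinc regulon (Zap1 targets) fell and 8 did not pass, with 7 called when adjusted over the list alone and a median of −0.31 (adjusted p = 4.98e-09, but adjusted p = 0.122 with an estimated correlation). Of 6 genes of the copper regulon (Mac1 targets), IRC7, FRE1 and CTR1 fell there and 3 did not pass, with 5 called when adjusted over the list alone and a median of −0.81 (adjusted p = 2.16e-08, but adjusted p = 0.151 with an estimated correlation). Of 12 hypoxic genes (Rox1 targets), 7 fell in the nHP strain comparison and 5 did not pass, with 7 called when adjusted over the list alone and a median of −0.40 (adjusted p = 0.000328, and adjusted p = 0.033 with an estimated correlation). The mannoprotein gene DAN1 fell by 2.54 ± 0.34 in nHP and rose by 4.04 ± 0.28 from nHP to HP in the mutation strain, with an interaction of 2.65 ± 0.39. Of 12 genes of endoplasmic reticulum folding, 8 fell from nHP to HP in the mutation strain and 4 did not pass, with 8 called when adjusted over the list alone and a median of −0.49 (adjusted p = 0.0008, but adjusted p = 0.226 with an estimated correlation). KAR2, the Hsp70 gene of that compartment, fell by 1.04 ± 0.11 there and had an interaction of −1.38 ± 0.15.

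The fall of a-specific and haploid-specific genes in the mutation strain is a pattern known from cells that express both mating types, in which a1 and alpha2 proteins repress haploid-specific genes. Weaker pheromone signalling alone would not account for the 5 haploid-specific genes outside the pheromone pathway, which had a median of −2.34 in nHP. These 5 were listed after the results were seen, with HO already among the largest falls in HP. The median therefore describes them and is no independent test. Libraries from a strain with intact LEU2 and MET17 are argued against, since LEU2 and MET17 had 0 counts among the 36842100 of the mutation strain libraries. Repression of the kind seen in cells that express both mating types stays open as a hypothesis, with a median of those 5 genes no higher than −1.83 in either comparison; the alpha genes of the mating type locus cannot show it, as MATALPHA1 and MATALPHA2 had 0 counts in all 8 libraries, with near-identical copies at HML that also had 0. An effect of the TAF10 excess itself cannot be told apart from one of the strain, because 0 of the 4 mutation strain libraries lack that excess.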
